A study of Mus musculus with 4 samples.

How the data were processed

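Single-nucleus RNA sequencing was carried out on whole brain without cerebellum from wild-type C57BL/6 mice aged 10 weeks. Per the labels' protocols the tissue was frozen on dry ice for 10 min, at most 50 mg of it entered each nuclear extraction, and libraries were made with a droplet kit (SeekOne DD) that tags the 3' end of each transcript with a unique molecular identifier (UMI). A group was defined by 2 factors. Harvest was either post-mortem, after cervical dislocation, or from the living animal by craniotomy under isoflurane anaesthesia. The nuclei were then either kept unfixed or fixed in 80% methanol at -20 °C for 30 min. Each of the 4 combinations holds 1 library, so no replicate check was possible, no test between groups was made, and a ratio compares 2 libraries and not 2 conditions. The labels do not state whether the fixed and the unfixed nuclei of a harvest came from 1 brain. Harvest cannot be separated from the animal or from the piece of tissue that was extracted.

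The values used were the deposited counts, whole-number UMIs per gene and barcode, with 32285 genes in every library, as the authors made them. The genome build was mm10 per the submitters' processing notes. The aligner, the cell caller, the annotation release and the strand setting of the counting were not given in the sources used here. Because that setting is unknown, genes that overlap a gene on the other strand, and antisense genes, are uncertain. Gene coordinates and types were taken from the GENCODE annotation of the same build, to which 32235 gene identifiers were matched.

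Nuclei were kept at 500 UMIs and 300 genes or more and with at most 5% of UMIs from mitochondrially encoded genes. Doublets were called per library with Scrublet in scanpy at an assumed rate of 6% and removed. Counts of the kept nuclei were log-normalised, 2000 variable genes were picked by their median rank over the libraries, and expression was centred and scaled within each library. Mitochondrially encoded, X-inactivation and Y-linked genes and Malat1 were left out of this step. Then 40 principal components, 20 exact nearest neighbours and Leiden clustering at resolution 1.0 gave the clusters. A cluster was named X-like when at least 3 markers of a class, and no fewer than 1 in 3 of them, were at least 2-fold higher in it than in the other nuclei and seen in at least 10% of its nuclei, and when its 10 leading genes held no more markers of another class. It stayed unnamed when its nuclei held a low number of UMIs and none of the class markers led it. The markers were fixed before the data were examined, as were the groups, comparisons, gene lists, thresholds and the rule for named genes. The naming rule was set after the cluster tables had been seen.

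UMIs were summed per library over all kept nuclei and over each named class, and scaled to the total of that sum (CPM). Classes were compared where every library held at least 100 nuclei and 100000 UMIs. Genes were compared at a mean CPM of at least 10, and within a class also at 50 UMIs or more. Fixation (methanol over unfixed) was compared within the post-mortem pair and within the anaesthetised pair, and harvest (anaesthetised over post-mortem) within the unfixed pair and within the methanol-fixed pair. A gene stood apart when it was at least 2-fold higher, or lower, in both pairs. Before a log2 ratio, 0.5 counts were added, and ratios are written in the order of the pairs above. Ratios of a gene carry exact conditional 95% intervals, its CPM values exact Poisson intervals and shares Clopper-Pearson intervals. These cover counting error only. Intervals of median UMIs rest on the ranks of nuclei. Those of genes per nucleus and of depth matched in steps of 100 UMIs come from resampled nuclei. Those of class profile distances come from resampled class counts. None of them covers differences between animals or libraries of a group. Against 0 counts a bound of 3 counts was used, per library.

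For each of 35 gene lists the median log2 ratio of its measured members was placed among 10000 random lists of equal size matched on mean CPM in 20 bins, as a description of these libraries. Lists with under 3 measured members were not summarised. The named genes were the 8 genes per direction and comparison with the largest smaller ratio of both pairs in all nuclei, the first 3 per direction in each class, and from each list up to 4 members with the highest CPM and up to 3 members that stood apart. Predicted symbols (Gm with digits, or ending in Rik) were counted and not named. Some genes with values in these tables are not reported here. Genes outside this rule, chosen after their values were seen, were the further immediate early genes of excitatory nuclei, Gabra2, the genes named as opposite-strand partners and the single markers counted in classes of another kind. To compare genes per nucleus across depths, each nucleus was thinned to 1000 UMIs, and shallower nuclei were left out.

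In simulated libraries with Poisson noise alone, 200 genes were set apart by known folds. For fixation in all nuclei, run on 9763 genes, 94.0% of genes set at 3-fold and 92.4% of those set at 4-fold were recovered, with 0 of 9574 unchanged genes called. For harvest in all nuclei, on 9760 genes, the shares were 94.0% and 93.9%. For fixation in microglia-like nuclei, on 6472 genes, they were 76.1% and 87.9%, with 4 of 6290 unchanged genes called, and for harvest in excitatory nuclei, on 9105 genes, 92.5% and 90.9%. No gene set at 1.5-fold was called in the 2 simulations of all nuclei.

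Alternatives were other nuclei filters, doublets kept, median-of-ratios size factors, totals without Malat1 and mitochondrially encoded genes, other CPM minimums, thinned sums, equal class weights, and other clusterings. Chosen after seeing the data were runs without nuclei over 100000 UMIs, without unnamed clusters, without genes that overlap a gene on the other strand, and with equal weight for each excitatory cluster. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0 and matplotlib 3.10.9. Sequence reads were not used here.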

Results

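The series compared 2 ways of collecting mouse brain and 2 ways of holding the nuclei before droplet capture, in a design with 1 library per combination. The question stated for it is how the harvest and a methanol step bear on single-nucleus transcriptomes. The deposited libraries held 14483 barcodes and 64312917 UMIs (post-mortem, unfixed), 17862 barcodes and 65591829 UMIs (anaesthetised, unfixed), 10843 barcodes and 82408017 UMIs (post-mortem, methanol), and 7650 barcodes and 75023578 UMIs (anaesthetised, methanol). After filtering, 12381, 15026, 9807 and 6802 nuclei were kept in the same order, with 51033740, 51560423, 65303519 and 59408368 UMIs. Scrublet marked 13.4%, 15.8%, 9.13% and 11.1% of the nuclei that passed the other filters.

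The methanol-fixed libraries held fewer nuclei and more UMIs in each. Median UMIs per nucleus were 3785 (95% interval 3699 to 3858) in the post-mortem unfixed library and 6291 (6207 to 6386) in its fixed partner, and 3019 (2963 to 3085) and 7812.5 (7617 to 7994) in the anaesthetised pair. Median genes per nucleus were 1950 and 2675, and 1608 and 3024. When every nucleus was thinned to 1000 UMIs, the order of genes per nucleus turned: medians were 680 in the post-mortem unfixed library, 679 in the anaesthetised unfixed one, and 662 and 663 after methanol. The fixed over unfixed ratio was 0.974 (0.972 to 0.976) in the post-mortem pair and 0.976 (0.973 to 0.976) in the anaesthetised pair. Nuclei under 1000 UMIs that were left out of this comparison numbered 1583, 2759, 693 and 351. Mitochondrially encoded genes took 0.0369% and 0.0335% of UMIs in the unfixed libraries and 0.0256% and 0.0240% in the fixed ones, after 183, 7, 51 and 1 barcodes over 5% were removed in the order post-mortem unfixed, anaesthetised unfixed, post-mortem fixed and anaesthetised fixed. Over every deposited barcode the shares were 0.121%, 0.0354%, 0.0319% and 0.0246% in that order.

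Excitatory neuron-like nuclei made up more of the anaesthetised libraries, 26.7% (26.0 to 27.4) unfixed and 27.2% (26.1 to 28.2) fixed, than of the post-mortem libraries, 20.9% (20.2 to 21.6) and 21.3% (20.5 to 22.1). With each library clustered separately the unfixed pair turned, to 16.7% under anaesthesia and 21.8% post-mortem. Medium spiny neuron-like nuclei, the projection neurons of the striatum, stood the other way, with 20.2% (19.5 to 21) and 17.4% (16.7 to 18.2) post-mortem against 14.5% (14.0 to 15.1) and 14.0% (13.2 to 14.9) under anaesthesia. Inhibitory neuron-like nuclei took 6.99%, 6.79%, 7.81% and 6.87% of the post-mortem unfixed, anaesthetised unfixed, post-mortem fixed and anaesthetised fixed libraries. In that order, oligodendrocyte-like nuclei took 11.9%, 12.6%, 15.7% and 13.1%, their precursors 1.35%, 1.93%, 1.79% and 2.15%, microglia-like nuclei 3.72%, 4.15%, 4.83% and 4.68%, and astrocyte-like nuclei 2.72%, 3.81%, 3.45% and 3.09%. Smaller named classes were newly formed oligodendrocyte-like, cholinergic neuron-like, endothelial-like, perivascular macrophage-like and fibroblast-like nuclei, each under 1% of every library. Clusters without a name held 29.4%, 27.3%, 25% and 26.8% of nuclei. The class profiles of the 2 harvests differed by 8.52% of nuclei (7.41 to 9.75) in the unfixed pair and 7.41% (6.05 to 9.03) in the fixed pair, and those of fixed and unfixed nuclei by 7.20% (6.00 to 8.5) in the post-mortem pair and 1.78% (1.20 to 3.35) in the anaesthetised pair. This order did not hold under other settings: fixation in the anaesthetised pair gave 12.5% when each library was clustered separately and 8.77% at 1000 UMIs or more, and harvest in the unfixed pair gave 5.46% with doublets kept, where fixation in the post-mortem pair gave 7.66%.

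**Figure D1:**
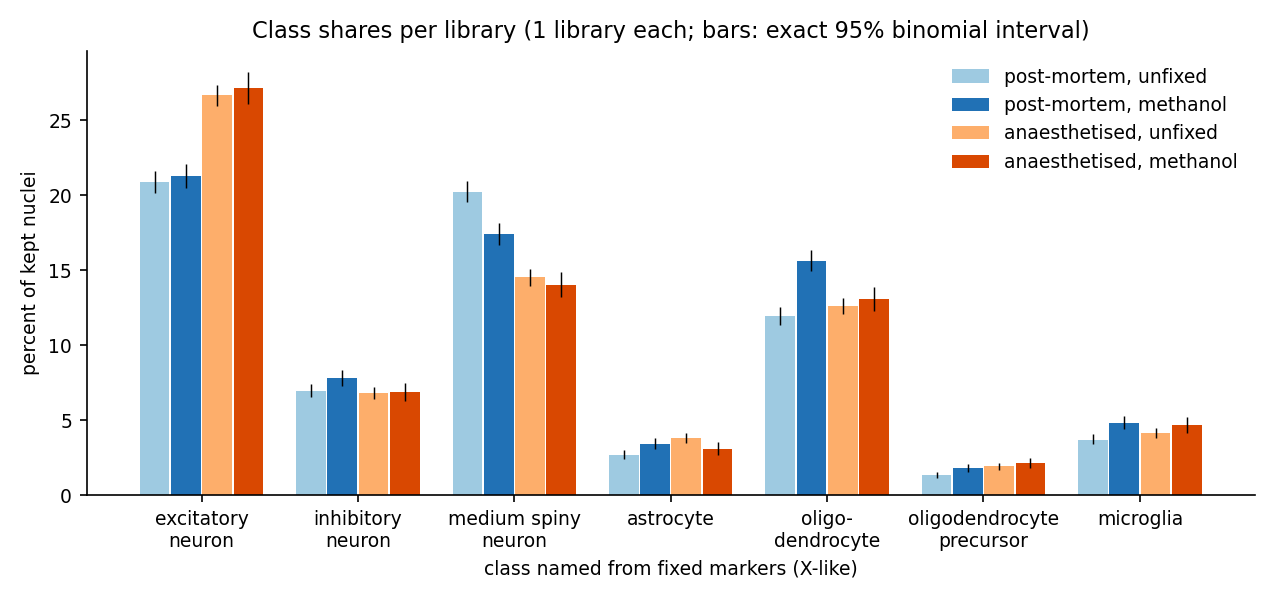
Share of kept nuclei (percent) in the 7 compared classes of each library, with exact 95% binomial intervals for counting error only. Excitatory neuron-like nuclei took 20.9% and 21.3% of the post-mortem libraries and 26.7% and 27.2% of the anaesthetised ones.

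Some clusters of the excitatory and inhibitory classes differed in share between the harvests. In the excitatory class, the cluster led by Ccbe1 and Smoc2 held 23.9% of post-mortem unfixed and 25.2% of post-mortem fixed nuclei and 24.4% and 25.2% of the anaesthetised ones, while a cluster led by Rorb, Adam33 and Rspo1 held 17.1% and 15.0% against 0.225% and 0.162%. Clusters led by Scn7a and Rspo2 (14.5% and 16.2% against 28.0% and 29.1%) and by L3mbtl4 and Fezf2 (5.65% and 3.26% against 13.5% and 13%) were larger under anaesthesia. In the inhibitory class a cluster led by Lhx6 and Lhx8 held 41.3% and 39.2% of post-mortem nuclei against 26.1% and 30.2%, and one led by Vip and Htr3a 14.1% and 14.6% against 24.3% and 21.2%. With 1 library per group, it could not be told whether a cluster held mostly by 1 harvest is a separate cell type or a feature of those libraries.

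Methanol fixation was compared first in all nuclei. Higher in the fixed libraries of both pairs were Gpr37l1, an astrocyte-enriched G protein-coupled receptor, at 8.43 and 26.3 CPM post-mortem and 5.97 and 14.3 CPM under anaesthesia (log2 1.64, interval 1.49 to 1.8, and 1.26, 1.07 to 1.45), and Rpa3, a subunit of replication protein A, at 9.99 and 27.3 CPM and 7.20 and 19.2 CPM (log2 1.45 and 1.42). Ssna1, a centrosomal protein gene, had 19.8 and 47.2 CPM, and 14.3 and 33.8 CPM. The orphan receptor Gpr22 was 1.30 and 1.31 log2 higher, the glycosyltransferase B4gat1 1.17 and 1.17, the snoRNA host gene Snhg8 1.19 and 1.40, and 2 genes for mitochondrial proteins, Slirp and Tomm6, 1.21 and 1.26, and 1.22 and 1.21. Lower in the fixed libraries were the ceramide synthase Cers1, at 62.8 and 12.4 CPM post-mortem and 56.9 and 12.4 CPM under anaesthesia (log2 -2.34, -2.46 to -2.23, and -2.20, -2.32 to -2.09), and the long non-coding RNA AY036118, at 557 and 135 CPM and 477 and 99.5 CPM (log2 -2.05 and -2.26). Of 9792 genes, 30 were at least 2-fold higher and 215 at least 2-fold lower in both pairs, and the ratios of the pairs correlated across genes at r = 0.943, where genes are not independent.

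Most genes that were lower after methanol lay over another gene on the opposite strand. This held for 204 of the 215, or 94.9%, against 37.7% of genes matched on expression, and 163 of the 215 were not protein-coding. Among the named ones, Lrtm1 (log2 -1.85 and -1.99) lies opposite Cacna2d3, a calcium channel subunit gene with 45.3 times its CPM. Rec114 (-1.81 and -1.72) lies opposite Nptn at 39.7 times, Angptl2 (-1.67 and -1.67) opposite Ralgps1 at 13 times, Angpt2 (-1.85 and -1.74) opposite Mcph1 at 8.19 times, Fndc9 (-1.82 and -1.81) opposite Cyfip2 at 4.39 times, and Rsph14 (-1.82 and -1.69) opposite Gnaz at 3.31 times. The erythroid haem enzyme gene Alas2 (-1.64 and -1.44) lies opposite Apex2 at 9.15 times its CPM. The partners of AY036118 and Cers1 had 2.05 and 0.233 times their CPM. Of the genes that were higher, Gpr22, Slirp and Tomm6 have such partners too, at 5.96, 3.45 and 2.30 times. Since the strand use of the counting is not given, UMIs of such pairs cannot be assigned to 1 gene with certainty. Without all genes that overlap another on the opposite strand, 19 genes were higher and 11 lower.

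In mm10, Cers1 (ENSMUSG00000087408, protein-coding) lies on chromosome 8 from 70315775 to 70331592 on the plus strand, AY036118 (ENSMUSG00000105361, lincRNA) on chromosome 17 from 39847113 to 39848035 on the minus strand, and Lrtm1 (ENSMUSG00000045776, protein-coding) on chromosome 14 from 29018208 to 29033645 on the plus strand. Rpa3 (ENSMUSG00000012483, protein-coding) lies on chromosome 6 from 8255936 to 8259173 and Gpr37l1 (ENSMUSG00000026424, protein-coding) on chromosome 1 from 135160234 to 135167681, both on the minus strand.

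**Figure D2:**
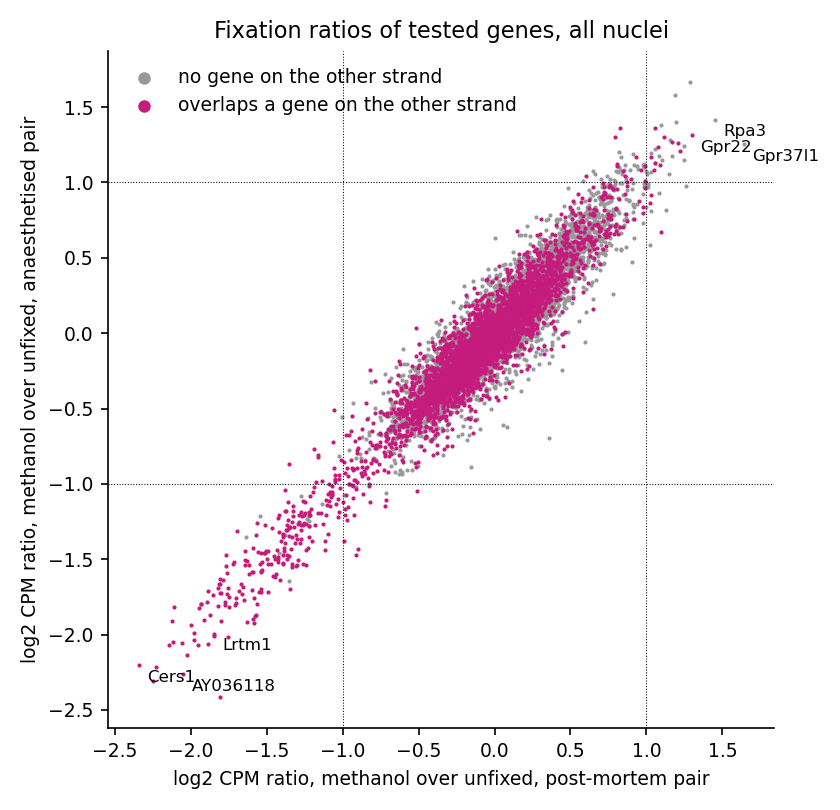
Log2 CPM ratio of methanol over unfixed for the 9792 genes tested in all nuclei, post-mortem pair on the horizontal and anaesthetised pair on the vertical axis; colour marks genes that overlap a gene on the other strand and dotted lines a 2-fold ratio. The points follow the diagonal (r = 0.943 across genes), and 204 of the 215 genes lower in both pairs are of the overlapping kind.

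Transcripts of the translation and respiration machinery were higher after methanol as groups in all nuclei. Of 53 measured genes for cytosolic ribosomal proteins, 49 were higher and 3 lower in both pairs, with medians of 0.61 and 0.84 log2 (above all random lists in both pairs). Rpl41, Rps21 and Rpl12 were at least 2-fold higher (1.03 and 1.20, 1.10 and 1.38, 1.12 and 1.30), while Rps27 was lower (-1.02 and -0.81). For nuclear-encoded oxidative phosphorylation 36 of 44 genes were higher and 5 lower in both pairs, with medians of 0.37 and 0.45, but in oligodendrocyte-like nuclei 7 of 46 were higher and 27 lower (-0.13 and -0.16) and in microglia-like nuclei 6 of 35 higher and 18 lower (-0.24 and -0.39). Abundant glial cytoplasmic transcripts had 16 of 20 members higher and 2 lower (medians 0.53 and 0.42), with the zinc-binding metallothionein Mt3 at 1.15 and 1.06, but the myelin gene Mbp at -0.37 and -0.63. Genes of the unfolded protein response had 13 of 15 members higher and 2 lower (medians 0.40 and 0.27), with the endoplasmic reticulum chaperone Hsp90b1 at 0.72 and 0.69. The glycolytic enzyme gene Gapdh was 1.09 and 1.12 higher, although the glycolysis list had medians of only 0.05 and 0.14.

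The mitochondrially encoded transcripts stood the other way, with 8 of 8 lower in both pairs (medians -0.50 and -0.43, percentiles 0.05 and 0.23), among them mt-Co3 at -0.54 and -0.51 and mt-Cytb at -0.67 and -0.71. An unnamed cluster of low UMI number led by Leng9 and mt-Co1 held 6.19% and 3.18% of unfixed but 0.51% and 0.456% of fixed nuclei, and within astrocyte-like nuclei the list medians were 0.02 and -0.42. Of the nuclear-retained RNAs 6 of 13 were higher and 6 lower. Meg3 had 12617 CPM unfixed and 8339 CPM fixed post-mortem, and 12111 and 8389 CPM under anaesthesia (-0.60 and -0.53), while Malat1 was nearly level at 0.04 and 0.16. Neuronal cytoplasmic transcripts had 23 of 31 members higher (medians 0.30 and 0.33), but their medians were -0.06 and -0.18 when classes were weighted equally. GABA-A receptor subunits (11 of 12 higher, medians 0.27 and 0.23) and long synaptic adhesion and channel genes (26 of 30 higher, 0.16 and 0.13) turned to -0.03 and -0.06 in the anaesthetised pair with these weights. The same held for heat shock genes in the post-mortem pair, from 0.18 to -0.02. Hypoxia genes had medians of -0.04 and -0.02, at percentiles 43.6 and 49.0. The split of 12.2% higher among the genes that stood apart was 20.2% with median-of-ratios factors and 35.7% with equal class weights.

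Within the neuronal classes, fixation set apart 80 genes higher and 209 lower of 9165 in excitatory, 44 and 175 of 9639 in inhibitory and 94 and 244 of 8892 in medium spiny neuron-like nuclei. In the medium spiny class Penk, the precursor of enkephalins, had 374 CPM unfixed and 1172 CPM fixed post-mortem and 259 and 1122 CPM under anaesthesia. Its log2 ratios were 1.65 (1.6 to 1.69) and 2.12 (2.05 to 2.19). The striatal receptor gene Gpr6 (12 and 57.4 CPM, and 8.77 and 62.0 CPM) was higher as well. Pde6a (-3.22 and -2.92), Mal (-2.75 and -2.63) and Cers1 (91.2 and 16.1 CPM, 81.0 and 15.6 CPM) were lower. Excitatory nuclei had higher AI413582 (4.76 and 15.1 CPM, 4.61 and 16.3 CPM), Tomm6 (5.23 and 17.0 CPM, 4.51 and 13.7 CPM) and Rpa3 (10.0 and 29.9 CPM, 6.05 and 18.6 CPM), and lower Cers1, Fndc9 and Ceacam2 (16.1 and 3.16 CPM, 18.3 and 3.62 CPM). In inhibitory nuclei the retinol carrier Rbp4 (8.75 and 26.1 CPM, 15.3 and 41.3 CPM), the ribosomal gene Rpl7a and the snoRNA host gene Snhg6 were higher, and Mal, Cers1 and AY036118 lower. Ribosomal protein genes had medians of 0.76 and 1.07 in excitatory, 0.65 and 0.84 in inhibitory and 0.78 and 1.02 in medium spiny nuclei.

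The glial classes were compared in the same way. In astrocyte-like nuclei Agt, the precursor of angiotensin, had 102 CPM unfixed and 1016 CPM fixed post-mortem and 30.3 and 279 CPM under anaesthesia (log2 3.31, 2.96 to 3.70, and 3.18, 2.55 to 3.91). There Gpr37l1 had 232 and 1641 CPM, and 128 and 1141 CPM, and Mfge8, a bridging protein of phagocytosis, 118 and 841 CPM, and 171 and 1103 CPM. Microglia-like nuclei had 1737 and 7558 CPM, and 1557 and 8308 CPM, of the protease inhibitor gene Cst3 (2.12 and 2.42), and 492 and 1887 CPM, and 461 and 1864 CPM, of the complement gene C1qb (1.94 and 2.01), with Emg1 higher as well. All 12 measured homeostatic microglial genes were higher in this class (medians 0.86 and 1.21, 5 at least 2-fold), as were 9 of 10 genes linked to ex vivo activation of microglia (0.66 and 1.26). Oligodendrocyte-like nuclei had higher Gpr62 (23.5 and 70.4 CPM, 15.6 and 73.6 CPM), Slc35b2 and Tmem258, and 13 of 16 myelin genes were higher (medians 0.45 and 0.83). Their precursors had higher Tmem176a (26.9 and 144 CPM, 8.86 and 143 CPM, from 10 and 4 unfixed UMIs), Tmem176b and Mfge8.

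Several neuronal gene lists were lower in oligodendrocyte-like and microglia-like nuclei of the fixed libraries. In oligodendrocyte-like nuclei 9 of 10 GABA-A receptor subunits were at least 2-fold lower (medians -1.59 and -2.48), as were 14 of 30 neuronal cytoplasmic genes (-0.88 and -1.16) and 6 of 7 striatal genes (-1.93 and -2.59). Akap5 had 45 and 1 UMIs post-mortem and 44 and 1 under anaesthesia (log2 -5.13, -11.04 to -3.15, and -4.41, -10.32 to -2.43). Sorbs2os, opposite to Sorbs2, stood at 24.6 and 2.83 CPM, and 21.1 and 2.32 CPM. In microglia-like nuclei 8 of 10 ionotropic glutamate receptor genes were at least 2-fold lower (-1.36 and -2.95). Slc4a3 had 37 and 3 UMIs, and 44 and 1, AI593442 36 and 2, and 23 and 1, and C1qtnf4 21 and 2 post-mortem, and 37 and 0 under anaesthesia, at least 8.53-fold lower. Astrocyte-like nuclei had lower Plppr4 (-2.55 and -2.79) and the granin gene Scg2 (-2.46 and -2.71), and precursor nuclei lower Grin2a (118 and 25 CPM, 88.6 and 19.7 CPM) and Il1rapl2, although GABA-A receptor subunits had medians of 0.14 and -0.07 in precursors. Altogether 151 genes were higher and 236 lower in astrocyte-like, 58 and 744 in oligodendrocyte-like, 68 and 93 in precursor and 122 and 450 in microglia-like nuclei. In oligodendrocyte-like nuclei the median of all genes was -0.13 and -0.12 with total UMIs and 0.07 and 0.08 with median-of-ratios factors, and in astrocyte-like nuclei -0.11 and -0.09 against 0.02 and 0.03.

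**Figure D3:**
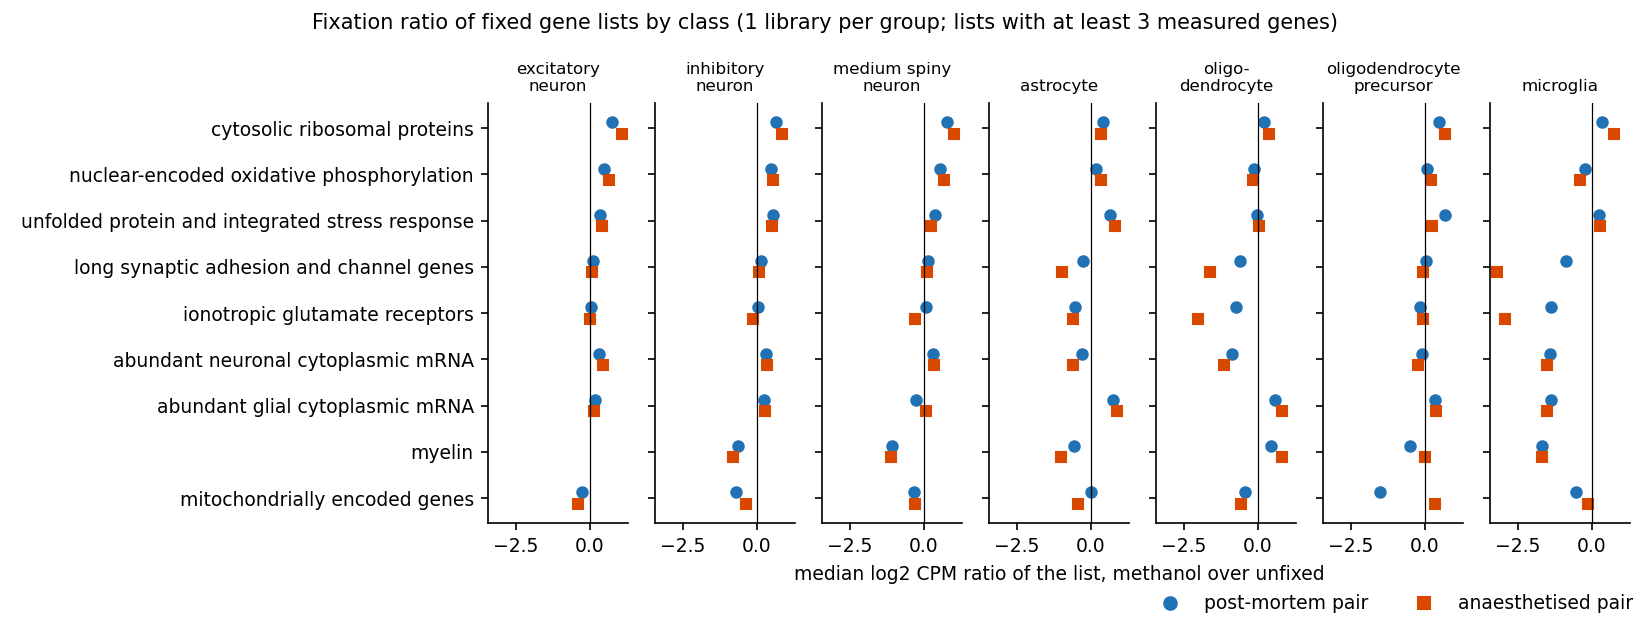
Median log2 CPM ratio, methanol over unfixed, of 9 fixed gene lists in each compared class; circles are the post-mortem and squares the anaesthetised pair, and lists with under 3 measured genes are left out. Ribosomal protein genes lay above 0 in excitatory nuclei (0.76 and 1.07), and ionotropic glutamate receptor genes below 0 in microglia-like nuclei (-1.36 and -2.95).

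Neuronal markers were counted in glial classes and glial markers in neuronal ones. The neuronal markers, 45 genes, took 0.321% and 0.363% of UMIs in oligodendrocyte-like nuclei of the unfixed libraries and 0.233% and 0.227% after methanol, and 0.263% and 0.354% against 0.141% and 0.0965% in microglia-like nuclei. In precursor nuclei the sum was not lower, with 0.902% and 0.927% unfixed and 0.95% and 0.969% after methanol, but the unfixed over fixed ratio was 3.87 and 15.1 for Nrgn, 3.36 and 8.88 for Penk and 5.81 and 2.62 for Slc17a7, from at most 65 UMIs in a library. The share of Slc17a7, the vesicular glutamate transporter, in oligodendrocyte-like nuclei was 6.68 and 14.5 times as high unfixed as fixed, that of the postsynaptic gene Nrgn 5.86 and 6.10 times and that of Penk 3.93 and 3.56 times. Glial markers in neurons differed less. The unfixed over fixed ratio of all 40 lay between 1.04 and 1.17 in the 3 neuronal classes, and that of Slc1a2, which neurons also transcribe, was 1.03 and 1.01 in excitatory nuclei. Median UMIs per nucleus were 1183 and 885 in unfixed and 1287 and 1377 in fixed oligodendrocyte-like nuclei, and 6270.5, 5050.5, 9929.5 and 12854 in excitatory ones.

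The harvest was compared next, as anaesthetised over post-mortem. In all nuclei, haemoglobin beta (Hbb-bs, log2 3.02, 2.81 to 3.25, unfixed and 1.96, 1.79 to 2.15, fixed), the orphan nuclear receptor Nr4a3, an immediate early gene (12.1 and 38.7 CPM, and 12 and 41.1 CPM; 1.68 and 1.78), and Zbtb16, a glucocorticoid-responsive transcription factor (48.6 and 130 CPM, and 40.1 and 108 CPM; 1.42 and 1.43), were higher under anaesthesia. Eif2s3y, a Y-linked translation factor gene, was 112-fold and 124-fold lower, at 83.6 and 0.737 CPM, and 120 and 0.960 CPM. The axon guidance receptor gene Robo3 was lower as well (-2.11 and -1.81). Of 9792 genes, 34 were at least 2-fold higher and 12 lower in both pairs, with r = 0.891 across genes. The share of higher genes, 73.9%, was 88.3% with median-of-ratios factors (53 higher and 7 lower) and 54.5% with equal class weights (6 higher and 5 lower), and without a minimum CPM the order turned (353 higher and 693 lower). The median of all genes was -0.10 and -0.09 with total UMIs and -0.14 and -0.12 without Malat1 and mitochondrially encoded genes in the total.

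Several of the leading genes also led clusters whose sizes differed between the harvests. These were Abi3bp (33.4 and 104 CPM unfixed) and the chloride channel Ano1 (7.33 and 23.6 CPM). Abi3bp led an unnamed cluster of 83 and 885 unfixed nuclei and Ano1 one of 164 and 606. Among the lower ones they were Rorb (207 and 102 CPM), Sfta3-ps (18.1 and 7.87 CPM), the endopeptidase gene Ecel1 (-1.19 and -1.23) in a cholinergic cluster of 72 and 39, and Dlk1 and AW551984, which led an unnamed cluster of 1853 and 949 unfixed nuclei. Rxfp1 (9.70 and 30.0 CPM) was higher although the excitatory cluster that it led held 3.09% and 2.73% of unfixed nuclei. The complement-like synaptic gene C1ql3 (1.70 and 1.39) was higher and Ddit4l (-1.42 and -1.43) lower. Nr4a3 (ENSMUSG00000028341) lies on chromosome 4 from 48045153 to 48086447 on the plus strand, Eif2s3y (ENSMUSG00000069049) on chromosome Y from 1010543 to 1028847 on the plus strand, and Hbb-bs (ENSMUSG00000052305) on chromosome 7 from 103826534 to 103828096 on the minus strand, all protein-coding.

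Immediate early genes, which neurons transcribe within minutes of activity, were higher under anaesthesia as a group. In all nuclei 19 of 21 were higher and 1 lower in both pairs, with medians of 0.44 and 0.63 log2, above all random lists. Excitatory nuclei had 19 of 23 higher and 3 lower, 7 of them at least 2-fold, with medians of 0.62 and 0.77. There Nr4a3 had 10.9 CPM post-mortem and 52.6 CPM under anaesthesia unfixed (2.27, 2.05 to 2.51) and 11.8 and 53 CPM fixed (2.16, 1.97 to 2.36). Fos had 9.88 and 24.8 CPM, and 15.0 and 45.0 CPM, Npas4 14.0 and 39.6 CPM, and 17.6 and 49.0 CPM, and Btg2 27.8 and 59.7 CPM, and 39.6 and 94.2 CPM. Egr3 (1.44 and 1.73), Egr4 (1.39 and 1.58) and Gadd45g (1.38 and 1.67) were also at least 2-fold higher, whereas Arc (0.29 and 0.53), Egr1 (0.39 and 0.89) and Bdnf (0.75 and 0.74) were less far apart. Inhba (-0.61 and -0.57), Nr4a2 (-0.40 and -0.81) and Klf10 (-0.15 and -0.52) were lower. Nr4a2 also led an excitatory cluster that held 14.8% and 15.9% of post-mortem excitatory nuclei (unfixed and fixed) against 10.2% and 8.66% of the anaesthetised ones. Medium spiny nuclei had medians of 0.08 and 0.20. The list was higher after methanol too in all nuclei, with medians of 0.38 and 0.47, although equal class weights gave -0.05 in the anaesthetised pair.

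**Figure D4:**
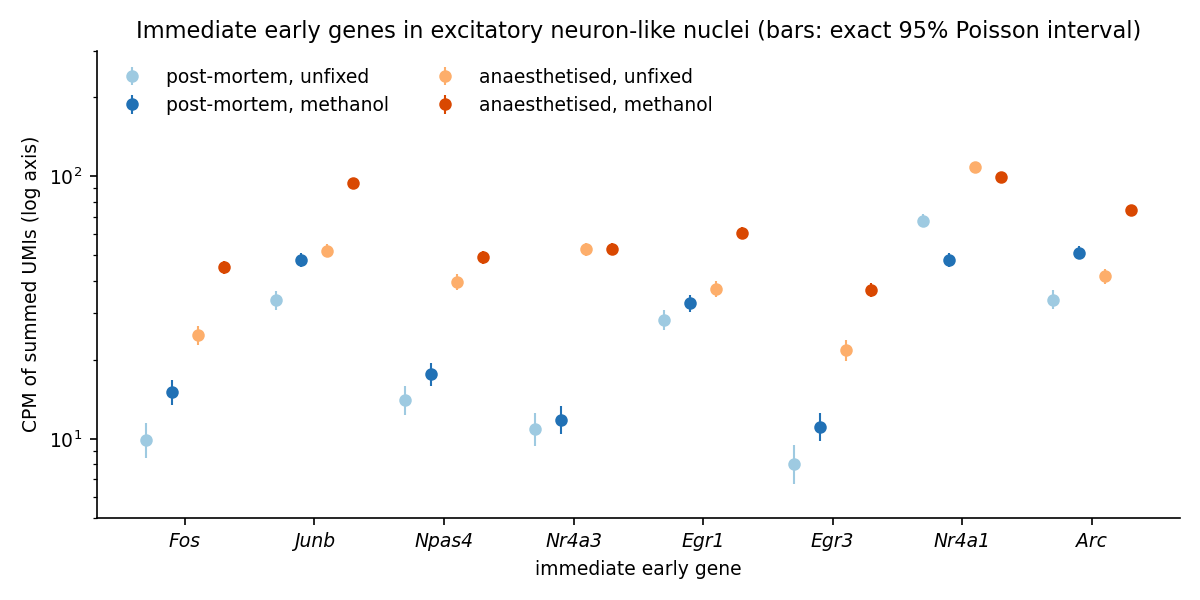
CPM (log axis) of immediate early genes in excitatory neuron-like nuclei of the 4 libraries, with exact 95% Poisson intervals for counting error only. Fos stood at 9.88 and 15.0 CPM in the post-mortem and at 24.8 and 45.0 CPM in the anaesthetised libraries.

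Striatal genes were lower under anaesthesia beside the lower share of medium spiny nuclei, with 10 of 10 lower in both pairs (medians -0.95 and -0.79), such as Penk at 167 and 80.9 CPM unfixed and 318 and 182 CPM fixed. Myelin genes were lower in 15 of 15 cases (-0.38 and -0.57, or 0.01 fixed with equal class weights), and oxidative phosphorylation genes in 44 of 44 (-0.31 and -0.18), although in oligodendrocyte-like nuclei 15 of 46 were higher and 12 lower, and medium spiny nuclei had -0.14 and -0.02. Ribosomal protein genes were lower in 46 of 53 cases (-0.31 and -0.10), but in the fixed pair no lower than random lists (percentile 77.4), heat shock genes in 14 of 17 (-0.28 and -0.17) and unfolded protein response genes in 14 of 15 (-0.25 and -0.28). Potassium channels linked to anaesthesia had 9 of 15 members higher and 5 lower (0.23 and 0.22, percentiles 99.9 and 100), but medians of only 0.11 and 0.02 in excitatory nuclei (percentiles 96.0 and 72.5) and 0.19 and -0.51 in oligodendrocyte-like nuclei. GABA-A receptor subunits, the main target of isoflurane, had medians of 0.04 and -0.02, and hypoxia genes -0.04 and -0.04. The Y-linked genes Uty (127 and 79.3 CPM, 148 and 90.7 CPM), Ddx3y (-0.68 and -0.57) and Kdm5d (-0.48 and -0.51) were lower by far less than Eif2s3y. Malat1 was lower too, at -0.50 and -0.38.

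Per class, harvest set apart fewer genes than fixation, 186 class and gene pairs higher and 129 lower against 617 and 2151, over the 7 classes. Excitatory nuclei held most of them (104 higher and 67 lower, r = 0.900 across genes), with the serotonin receptor gene Htr4 (6.53 and 30.8 CPM, 6.07 and 33.1 CPM) and L3mbtl4 (14.5 and 60.8 CPM, 9.85 and 53.3 CPM) higher, and Pld5 (93.5 and 14.7 CPM, 79.4 and 13 CPM) and the collagen gene Col11a1 (56.6 and 11.8 CPM, 49.5 and 5.14 CPM) lower. The mix of excitatory clusters differed between the harvests, so these class ratios do not separate it from differences within a cluster. L3mbtl4 led a cluster of 5.65% and 3.26% of post-mortem excitatory nuclei (unfixed and fixed) against 13.5% and 13% of the anaesthetised ones. Inhibitory nuclei had higher Cck, a neuropeptide (33.9 and 104 CPM, 32.4 and 138 CPM), and lower Hapln4 and Adamtsl5. Medium spiny nuclei had lower Cnr1, the cannabinoid receptor (121 and 41.8 CPM, 196 and 45.9 CPM), and Acvrl1, and higher Stard13. The mix of this class differed too: its cluster led by Drd2 held 8.88% and 7.56% of all post-mortem nuclei (unfixed and fixed) and 8.54% and 8.87% of the anaesthetised ones, and its cluster led by Sh3rf2 11.3% and 9.85% against 6.00% and 5.17%. In astrocyte-like nuclei Hs3st3a1 (13.5 and 71.2 CPM, 7.01 and 70.2 CPM) and Tmem132b were higher and Agt lower (-1.73 and -1.86). The transthyretin gene Ttr, a choroid plexus product, had 9 and 0 UMIs, and 72 and 0, at least 3.41-fold and 15.8-fold lower. Eif2s3y was lower in all 7 classes, in astrocyte-like nuclei from 71 UMIs to 0 and from 104 to 0, at least 26.9-fold and 22.8-fold.

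Haemoglobin transcripts, the products of red blood cells, were higher under anaesthesia in oligodendrocyte-like nuclei. There Hbb-bs had 10.9 and 82.8 CPM, and 12.3 and 34.1 CPM, and Hba-a1 and Hba-a2 were higher with it (medians of the 3 genes 2.89 and 1.81). Genes were named in a class only where they stood apart, so naming does not speak for the other classes. In the same class the hypothalamic peptide gene Oxt (73 and 18 UMIs, and 11 and 0, at least 2.24-fold) and the striatal gene Ppp1r1b (33.3 and 15.0 CPM, 12.8 and 4.65 CPM) were lower. Microglia-like nuclei had lower mitochondrially encoded transcripts (6 of 8 at least 2-fold, medians -1.79 and -1.35), such as mt-Co3 (233 and 56.1 CPM, 164 and 49.3 CPM) and mt-Nd1 (-1.88 and -1.73), and higher Mical2 and Fam107b, while the same list was higher in excitatory nuclei (0.46 and 0.32). Precursor nuclei had higher Zbtb16 (40.4 and 117 CPM, 20.8 and 68.0 CPM), Trank1 and Knl1 and lower Mettl2 and Fzd9. In the glial classes the pairs shared little: across genes, r was 0.209 in astrocyte-like, 0.0885 in precursor, 0.00415 in oligodendrocyte-like and -0.117 in microglia-like nuclei.

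The fixation ratios of the 2 harvests were compared gene by gene. In all nuclei Hbb-bs was the only gene of 9792 whose ratios differed by at least 1 log2, at 0.36 in the post-mortem and -0.70 in the anaesthetised pair, but with equal class weights 47 genes did. The number was 4 in excitatory, 36 in inhibitory and 11 in medium spiny nuclei, and 832 in astrocyte-like, 808 in oligodendrocyte-like, 709 in precursor and 1019 in microglia-like nuclei, whose summed UMIs were far fewer.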

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

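The tests of less free RNA, of depth in microglia-like and astrocyte-like nuclei and in steps of 100 UMIs, of loss of free RNA, of a lower yield of non-coding RNA and of the mix of excitatory clusters were chosen only after the result was seen, as were the patterns weighed here; the tests of depth in oligodendrocyte-like nuclei thinned to 800 UMIs, of overlapping genes and of scaling were written before.

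Synaptic gene lists differed between the harvests in opposite directions in the unfixed and the methanol-fixed pair of 2 glial classes. Only lists with at least 5 measured genes and medians of at least 0.5 log2 in size in both pairs were counted. Smaller opposite differences are left out here. In oligodendrocyte-like nuclei GABA-A receptor subunits had a median anaesthetised over post-mortem log2 ratio of 0.56 unfixed and -0.58 fixed. In microglia-like nuclei the medians were 0.88 and -0.55 for GABA-A receptor subunits, 1.11 and -0.80 for ionotropic glutamate receptors, and 1.28 and -1.03 for long synaptic adhesion and channel genes. With 1 library per group these differences were not tested. The share of UMIs from the 45 neuronal markers had the same order in microglia-like nuclei. It was 0.263% post-mortem and 0.354% under anaesthesia unfixed, and 0.141% and 0.0965% fixed. In oligodendrocyte-like nuclei it was 0.321% and 0.363% unfixed, and nearly level at 0.233% and 0.227% fixed. Expression by the glia and neuronal transcripts from outside the nucleus were not told apart for these lists. In the post-mortem fixed library 19 barcodes held more than 100000 UMIs each, against 0 in its unfixed partner, and 4 of them were kept. Without these 4 the fixation counts in all nuclei were 27 higher and 216 lower. Outside the comparisons, 183 barcodes of the post-mortem unfixed library lay over the mitochondrial limit.

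The share of neuronal markers was lower in oligodendrocyte-, microglia- and astrocyte-like nuclei of the fixed libraries, while in precursor nuclei the sum of markers was not lower but Nrgn, Penk, Slc17a7 and Gad2 were. Nuclear depth as the whole cause is argued against in microglia-like nuclei only, by a test chosen after the result was seen. Among their nuclei of 800 to 2000 UMIs thinned to 800, the unfixed share was still 1.95 and 3.61 times the fixed share. The lower bounds, 1.63 and 2.88, lay above the 1.5 used for exclusion. In oligodendrocyte-like nuclei the same ratios were 1.39 and 1.56 (lower bounds 1.29 and 1.42). The post-mortem ratio missed the 1.5 in both pairs set beforehand, so this test did not exclude depth there. Matching in steps of 100 UMIs, chosen afterwards, left these ratios at 1.39 and 1.5, with lower bounds of 1.32 and 1.41. The unfixed share thus stayed higher at like depth, but by less than the rule asked for in the post-mortem pair. In astrocyte-like nuclei depth and the fixation cannot be told apart, because ratios of 1.27 and 1.40 had lower bounds of 1.05 and 1.15. Less free RNA stays open too: glial markers should then be lower in neurons by at least 0.5 log2. They were lower, with medians of -0.62 and -0.75 in medium spiny, -0.42 and -0.49 in excitatory and -0.23 and -0.46 in inhibitory nuclei. The highest of the 6, -0.23, lay between the bounds set.

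The 215 genes that were at least 2-fold lower after methanol in both pairs of all nuclei overlapped a gene on the other strand 2.52 times as often as tested genes matched on expression (94.9% against 37.7%). A general lower yield of non-coding RNA is argued against, since 185 non-coding genes without such an overlap had medians of 0.041 and 0.023, while 435 with one had -0.62 and -0.63. A candidate explanation is that UMIs counted for these genes came in part from transcripts of the opposite gene, and that methanol lowers that part. It stays a hypothesis, because the strand use of the counting is not given and Cers1 has a partner at only 0.233 times its CPM. Loss of free RNA and this explanation cannot be told apart, because the medians of -1.35 or below in the 3 neuronal classes come from classes that hold 63.9% of the UMIs by which the genes were chosen.

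Immediate early genes were higher in excitatory neuron-like nuclei of the anaesthetised libraries. A different mix of excitatory clusters as the whole cause is argued against, since equal weight for each cluster with at least 50 nuclei in every library left medians of 0.53 and 0.83. Scaling is argued against as well, since median-of-ratios factors gave 0.70 and 0.83. Neuronal activity during anaesthesia or surgery and the time from death to freezing stay open and untested. So do the animal itself and the piece of brain that was extracted, since each of these goes with the harvest.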

How the results depend on the processing

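The runs without nuclei over 100000 UMIs, without unnamed clusters, without genes overlapping another on the opposite strand, and with equal excitatory cluster weights were tests chosen only after the result was seen. The fixation counts in all nuclei, 30 higher and 215 lower, became 4 and 28 at a mean CPM of at least 50 and 404 and 1830 without a CPM filter, where fewer or more genes were compared. The higher count became 50 with median-of-ratios factors, 111 with equal class weights and 49 without unnamed clusters, and without overlapping genes the counts were 19 and 11. Per class, 617 higher became 251 at 50 CPM, and 2151 lower became 517 at 50 CPM and 3808 without the filter. The harvest counts in all nuclei, 34 and 12, became 53 and 7 with median-of-ratios factors, 8 and 2 at 50 CPM, 353 and 693 without the filter and 6 and 5 with equal class weights, and the higher count 56 without unnamed clusters. Per class, 186 higher became 49 at 50 CPM, 372 without the filter and 331 with each library clustered separately, and 129 lower became 35 and 424 with the 2 filters. The distance of class shares between fixed and unfixed nuclei became 4.92% post-mortem, from 7.20%, and 12.5% under anaesthesia, from 1.78%, with separate clustering; the latter was 8.77% at 1000 UMIs or more and 3.54% with doublets kept. For harvest in the unfixed pair 8.52% became 9.92% without scaling within each library, 13.3% with separate clustering and 5.46% with doublets kept. Over every deposited barcode, median UMIs were 3968, 3204, 6511 and 8378.5 in the order post-mortem unfixed, anaesthetised unfixed, post-mortem fixed and anaesthetised fixed. Thinning to 2000 UMIs gave fixed over unfixed gene ratios of 0.982 post-mortem and 0.985 under anaesthesia. Non-additivity of at least 1 log2 was found for 1 gene, for 2 with median-of-ratios factors and for 47 with equal class weights. With equal class weights these fixation medians turned: GABA-A receptor subunits (anaesthetised pair, -0.031), neuronal cytoplasmic transcripts (-0.056 and -0.18), heat shock genes (post-mortem pair, -0.024), immediate early genes (anaesthetised pair, -0.054) and long synaptic genes (anaesthetised pair, -0.065). In the fixed harvest pair, myelin turned to 0.012 and RNA processing genes to 0.043 with these weights and to 0.0027 with median-of-ratios factors. For these moved and turned results the cause was not tested, except that equal class weights remove the class shares by construction. Of 112 single class shares 61 moved, by more than their counting interval. Of 320 list medians 246 stayed within their spread, 65 moved and 9 turned. The compared glial classes held fewer summed UMIs than the neuronal ones, and some single genes there rest on few UMIs.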

Other observations

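The per-cluster values of immediate early genes and the tests on hydrophobic segments and Gabra2 below were chosen only after the result was seen, except that the bound for the segments was written before that comparison.

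Within the excitatory class, immediate early genes were higher under anaesthesia in most clusters that could be compared, though not equally. The cluster of 618, 979, 525 and 466 nuclei had list medians of 1.03 unfixed and 1.10 fixed, with Fos at 5.46 and 19 CPM, and 7.53 and 41.2 CPM, and Nr4a3 at 5.23 and 39.5 CPM, and 5.6 and 30.1 CPM. The cluster led by Scn7a and Rspo2 had 0.74 and 1.04, and that led by L3mbtl4 and Fezf2 0.91 and 1.17. The cluster led by Nr4a2, Ntng2 and Rxfp1 had only 0.03 and 0.33.

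Other gene groups were compared as well. Gabra2, a GABA-A receptor subunit gene, had 250, 276, 306 and 351 CPM in the post-mortem unfixed, anaesthetised unfixed, post-mortem fixed and anaesthetised fixed libraries. Ionotropic glutamate receptor genes had harvest medians of 0.17 and 0.15 (9 of 16 higher and 6 lower in both pairs) in all nuclei and 0.36 and 0.25 in excitatory nuclei (percentiles 99.6 and 98.9). Synaptic vesicle genes had 0.05 and 0.06, and cortical genes 0.01 and -0.01 in all nuclei but -0.20 and -0.28 in excitatory nuclei, where 10 of 13 were lower. Clock genes had -0.16 and -0.13 (percentiles 12.3 and 18.4), and glucocorticoid-responsive genes 0.08 and 0.03, with Zbtb16 the 1 member of 7 at least 2-fold higher. Genes of the p53 and cell death list had fixation medians of 0.06 and 0.07. Hippocampal genes had harvest medians of 0.57 and 0.45 within excitatory nuclei, at or near the top of the random lists (percentiles 100 and 99.99). The mix of excitatory clusters differed between the harvests, and the hippocampal and cortical lists were not compared cluster by cluster.

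An unnamed cluster led by Top2a, Igfbpl1 and Mki67, genes of dividing cells and neuroblasts, held 37 nuclei of the post-mortem unfixed, 414 of the anaesthetised unfixed, 31 of the post-mortem fixed and 210 of the anaesthetised fixed library. Another, led by mt-Co1 and Leng9 and of low UMI number, held 766, 478, 50 and 31 nuclei in the same order.

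Whether transcripts that encode a hydrophobic segment were higher after methanol in glia was examined against a bound of 0.3 log2 written beforehand, which was not reached. The median difference from genes without such a segment lay between 0.04 and 0.23 over the 4 glial classes and 2 pairs, and between 0.03 and 0.28 when genes were matched on length.

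The difference of Eif2s3y between the harvests was not shared by the other Y-linked genes. Eif2s3y was 112-fold lower unfixed and 124-fold lower fixed, while Uty had log2 ratios of -0.68 and -0.71 and Kdm5d of -0.48 and -0.51. Gabra2, whose level differs between C57BL/6 substrains, was examined beside it: it was 1.41 and 1.37 times as high under anaesthesia in excitatory nuclei, but its log2 ratios were 0.05 and 0.09 in medium spiny nuclei. Nothing was decided about the animals from these values.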
